A study of Chlamydomonas reinhardtii with 32 samples.

How the data were processed

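Total RNA of whole cells of the green alga Chlamydomonas reinhardtii, strain CC-124, was labelled with the dye Cy3 and hybridised to 32 single-colour Agilent oligonucleotide arrays, per the labels. The array signals were brightness values on a linear scale, deposited as scanner output. Per the file headers, the processed intensity was made with Agilent Feature Extraction 9.5.3.1 under the protocol GE1-v5_95_Feb07, which subtracted the background and removed spatial trends within an array and did no scaling between arrays. Mean spot intensity and median local background intensity were deposited beside it. The other deposited columns used were flags of 0 or 1 per spot, which per the file headers marked spots well above background, saturated spots and outlying spots. A separate table of log2 values from the authors covered the same arrays. Each of its probes had a median of 0 over the arrays, the medians of its columns lay between -0.34 and 0.44, and after centring each probe its columns correlated across probes at 0.990 to 1.000 with the values computed here. Its steps are not given in the sources used here, so scale and direction were taken from that match, and it served as an alternative only.

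Each array held 15744 features. After removal of 536 control spots, 15208 spots of 10000 probes of 45 to 60 nt remained, and 5208 probes had 2 spots. Outlying spots (6 to 305 per array) were left out and the spots of a probe were averaged. Values are log2 of the processed intensity minus the 75th percentile of the array, so that 0 is that percentile. A probe was kept if it was well above background on all arrays of at least 1 group, which left 8475 probes, of which 42 lacked a value in some group. 4942 probes were well above background on all arrays. The files give each probe a number and a letter and no gene: the gene name column repeats the probe name, the description reads Unknown, and 0 of the 10000 names matched the 17742 genes of the reference table used here. Results are therefore given per probe, with probe sequences as the files list them. The 20 gene lists fixed beforehand, their shifts and the averaging of probes per gene were not run for this reason.

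Groups were the 12 combinations of addition (none, hemin or Mg-protoporphyrin) and time, with 4 arrays in control 60 min, control 120 min, hemin 120 min and Mg-protoporphyrin 60 min, and 2 arrays in each other group. Per the design text the feeding was carried out and then repeated, so groups of 4 may hold arrays of a shared culture, and the labels do not say which. The p-values then measure the spread between arrays, which may be technical. A plan to average such arrays was dropped because it required both pairs in sequence to be the closest in each of these groups, and arrays 3 and 4 were not, while arrays 1 and 2 were in 3 of the 4 groups. All 32 arrays entered as separate samples. Comparisons were made with limma 3.58.1 in R 4.3.3, with 1 linear model for the 12 groups (20 residual and 3.29 prior degrees of freedom), moderated variances and Benjamini-Hochberg adjustment per comparison. A probe was called at an adjusted p under 0.05. Values were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The number of arrays limits the precision.

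The rule for printed probes was fixed before the data were examined: the called probes with the highest and the lowest log2 changes whose arrays did not overlap between the groups. Its requirement of a gene name could not be met. The rule was instead applied to probes that were well above background and not saturated on all arrays of both groups, and at most 2 probes that rose and 2 that fell are printed per comparison. The same rule was applied to the comparison of the compounds. Any other probe was chosen after its values were seen, and this is stated beside it.

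The steps were tested on simulated data for 8027 probes, 200 of them changed by known amounts. Of probes changed by 2 on the log2 scale, 74% were recovered for Mg-protoporphyrin at 60 min, 48% at 120 min and 30% at 180 min, and for hemin 50%, 72% and 38%. Of the simulated calls, 1.70% to 7.77% were false. Most of the real comparisons called a larger share of probes than was changed here, which loosens the adjusted threshold. The simulated arrays also varied independently, which arrays of a shared culture do not. Recovery and false calls in the data may therefore differ from these shares. Because hemin and Mg-protoporphyrin were compared with the same control arrays, unchanged groups were simulated 100 times against those controls to give the correlation that shared controls bring by themselves.

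The arrays lay on 4 slides of 8, each scanned once, and slides held arrays of several groups. Slide was therefore tried as a block, and changes were also computed within slides. The share of called probes with the pooled direction within a slide uses the same arrays that gave the calls, so it is high almost by construction and does not test independence from slide. The labels number the arrays in each group. Deviations from the group means of equally numbered arrays correlated across probes at 0.55 to 0.67 between hemin and control at 120 min and at 0.36 to 0.73 between Mg-protoporphyrin and control at 60 min, in each of the 4 pairs. By the rule fixed for this check the numbers pair the arrays in these 2 comparisons. That pairing comes from the data and is partly that of shared slides. Unequally numbered arrays were not compared, so the check cannot show that the numbers themselves pair the arrays. Alternatives fixed before the data were examined were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, the authors' log2 values, no filter and a stricter filter on dim probes, averaged arrays, replicate and slide blocks, a fit of the compared groups alone, changes from the own 0 min samples, and leaving out each array in turn. Chosen after seeing the data were averaging arrays 1, 2 and 4 of each group of 4, the same with a replicate block, that design with scaling on the spike-in RNA, leaving out the 3 arrays with the largest differences between the spots of a probe, and a block on the numbers 1 to 4. The spike-in values rest on 4 of 10 spike-in probes, those above background and unsaturated on all arrays.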

Results

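The series asked how gene expression in Chlamydomonas reinhardtii changes when tetrapyrroles are fed to dark-kept cells. Hemin is protoporphyrin with iron at its centre, and Mg-protoporphyrin (MgProto) is protoporphyrin with magnesium, an intermediate of chlorophyll synthesis. Cells of strain CC-124 grown at 23 °C in acetate medium were kept in the dark for 16 h as 25 ml cultures, received 9 µM hemin, 9 µM MgProto or nothing, and were harvested in the dark at 0, 60, 120 and 180 min. Transcript levels were measured on 32 arrays in 12 groups, with 4 arrays in control 60 min, control 120 min, hemin 120 min and MgProto 60 min and 2 arrays in each of the other 8 groups. The 75th percentile of the processed intensity ranged from 1153 to 5376 between arrays, and 59.9% to 88.4% of spots lay well above background (median 71.4%). The spots of a probe spotted 2 times differed by a median of 0.07 to 0.24 on the log2 scale within an array.

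The arrays separated first by treatment. The first principal component held 59.5% of the variance and set hemin arrays from 60 min on and MgProto arrays at 60 min apart from the control and 0 min arrays, with MgProto arrays at 120 and 180 min between them. The second component held 14.0% and ran across the arrays within groups. In groups of 2 the arrays differed by a median absolute log2 difference of 0.49 to 0.62. In groups of 4, array 3 differed from the others by 0.45 to 0.84, and the others from each other by 0.19 to 0.45.

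**Figure D1:**
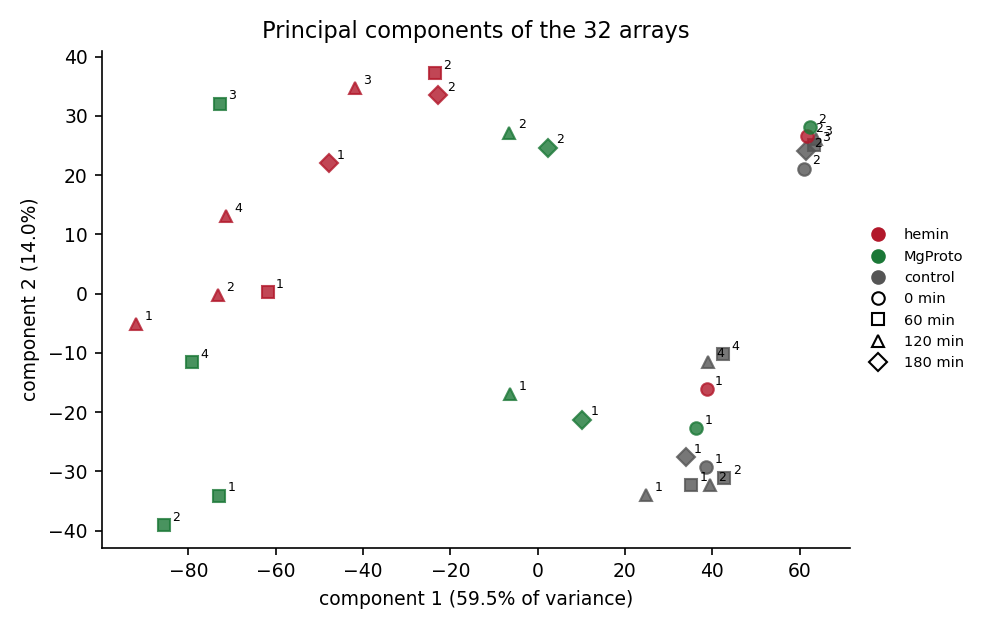
Principal components of the 32 arrays, with the first component (59.5% of variance) on the x axis and the second (14.0%) on the y axis, coloured and marked by treatment and time. MgProto arrays at 60 min lie between -85.6 and -72.9 on the first component, and those at 180 min at 2.44 and 10.2.

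Before the compounds had time to act, and in cells that received none, no probe was called in the main comparisons. At 0 min limma with Benjamini-Hochberg adjustment called 0 probes for hemin against control and 0 for MgProto against control, with 67 and 46 probes at an unadjusted p under 0.05. Hemin against MgProto at 0 min likewise gave 0 calls, with 23 probes at an unadjusted p under 0.05. In control cells 0 of 8447 probes were called over the 4 times by limma, with 116 at an unadjusted p under 0.05, and 0 probes were called between 0 min and 60, 120 or 180 min, with 114, 138 and 137 at an unadjusted p under 0.05. Leaving out array 2 of control 180 min raised the count over time to 44. With slide as a block each of the 0 min counts and the count over time was again 0. In the main fit each unadjusted count was under the share of 0.05 that chance gives over the tested probes. The test was thus conservative here, and 0 calls are weak evidence that nothing differed.

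After 60 min with hemin, 1843 probes were higher and 1202 lower than in control cells, out of 8473 tested. The change was large for many of them: 1697 rose and 1132 fell at least 2-fold, and 337 rose and 145 fell at least 8-fold. The largest changes named here and below are those among the probes that the rule for printed probes ranks. Probe 1793.C (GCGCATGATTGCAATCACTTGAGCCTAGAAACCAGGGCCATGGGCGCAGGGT) had the largest rise, from -3.62 ± 0.95 (SD, n = 4) in control to 5.84 ± 0.51 (n = 2) on the log2 scale relative to the 75th percentile, a log2 change of 9.46 (SE 1.01, limma adjusted p 1.71e-07) or 705-fold. Probe 5713.C (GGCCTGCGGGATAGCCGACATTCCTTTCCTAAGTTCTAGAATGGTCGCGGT) rose 282-fold, by 8.14 (SE 0.86, limma adjusted p 1.50e-07). Probe 3098.C (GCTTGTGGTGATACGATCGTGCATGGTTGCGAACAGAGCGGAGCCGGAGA) fell by 5.55 (SE 0.63, limma adjusted p 3.68e-07) or 46.9-fold (25.7 to 85.8 on leaving out each array in turn), and probe 6274.C (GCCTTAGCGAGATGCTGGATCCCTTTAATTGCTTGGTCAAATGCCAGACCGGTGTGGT) fell by 5.32 (SE 0.38, limma adjusted p 9.55e-10). 57 called probes were well above background on all hemin arrays and on no control array. For 84 the reverse held, so that the fitted folds of both sets are not measured sizes. Only 2300 of the 3045 called probes were well above background on all arrays of both groups. The 2-fold and 8-fold counts also cover the others. The median over all probes was 0.28, and with quantile normalization it was -0.03 while 1696 probes were called higher and 1584 lower. The median change was 0.88 in the probes highest in GC content and 0.05 in those lowest. Whether GC content adds to the excess of rises was not tested. With slide as a block 4084 probes were called, and on the 1 slide that held both groups 99.5% of the called probes had the pooled direction. Without array 1 of hemin 60 min the count was 1599, and 1240 probes were called when changes from each treatment's own 0 min arrays were compared.

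After 120 min with hemin 2041 probes were higher and 1916 lower than control of 8471 tested, with 4 hemin arrays here and 2 at 60 min, and 1771 rose and 1736 fell at least 2-fold. The share of called probes among those tested was 46.7%. Among the ranked probes 1793.C again had the largest rise, to 5.95 ± 0.33 (SD, n = 4) against -2.87 ± 1.51 (n = 4) in control. Its log2 change was 8.82 (SE 0.82, limma adjusted p 1.00e-08). Probe 697.C (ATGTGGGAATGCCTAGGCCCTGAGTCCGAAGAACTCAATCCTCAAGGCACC) rose by 7.13 (SE 0.39, limma adjusted p 5.53e-12), which is 140-fold. Probe 3098.C fell by 6.94 (SE 0.51, limma adjusted p 5.05e-10), a 123-fold fall, and probe 9558.E (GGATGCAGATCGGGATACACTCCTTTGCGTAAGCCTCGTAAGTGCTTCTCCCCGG) fell by 6.38 (SE 0.83, limma adjusted p 1.06e-06). With arrays 1, 2 and 4 averaged and a replicate block the counts were 3729 at 60 min and 3579 at 120 min. Within the 2 slides that held both groups 99.9% and 100% of the called probes had the pooled direction, and slide as a block gave 5274 calls. Slide 1 alone, with 4 arrays of these 2 groups, gave 4715 calls, of which 3720 were also called with all arrays. Those 4 arrays are among the arrays that gave the full calls, so this overlap is not a replication. Counts were 2632 with arrays 1 and 2 and arrays 3 and 4 averaged, 2331 with arrays 1, 2 and 4 averaged, and 2023 against the own 0 min arrays.

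After 180 min with hemin 969 probes were higher and 839 lower than control of 8464 tested. Probe 1793.C still stood at 5.02 ± 0.01 (SD, n = 2) against -3.07 ± 1.505 (n = 2), a change of 8.10 (SE 1.16, limma adjusted p 4.01e-05). Probe 5713.C rose by 7.48 (SE 0.99, limma adjusted p 2.28e-05). Probe 9558.E fell by 7.01 (SE 1.18, limma adjusted p 0.000194), a 129-fold fall (48.3 to 346 on leaving out each array in turn), and probe 6066.C fell by 6.73 (SE 1.49, limma adjusted p 0.00226). The limma adjusted p of 6066.C was 0.0937 against the own 0 min arrays and 0.0569 without array 1 of hemin 180 min. Over the 3 times 722 probes were called higher and 506 lower at each of them. With slide as a block 3341 probes were called, and on the 1 slide that held both groups 100% of the called probes had the pooled direction. The count was 1060 without array 2 of control 180 min, 793 without array 1 of hemin 180 min, 351 with the compared groups alone in the fit and 523 against the own 0 min arrays.

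MgProto gave its widest response at 60 min. 2116 probes were higher and 2232 lower than control of 8469 tested, 51.3% of them, and 384 rose and 699 fell at least 8-fold. Probe 5713.C, which also rose with hemin, went from -0.76 ± 1.23 (SD, n = 4) to 5.94 ± 0.37 (n = 4), a change of 6.69 (SE 0.70, limma adjusted p 2.75e-08) or 104-fold. Probe 3727.C (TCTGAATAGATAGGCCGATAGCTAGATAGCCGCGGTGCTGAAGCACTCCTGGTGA) rose by 6.42 (SE 0.38, limma adjusted p 1.57e-11), 85.6-fold. Probe 9383.E (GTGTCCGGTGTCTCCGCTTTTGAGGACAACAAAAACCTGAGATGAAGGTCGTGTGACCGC) fell by 6.89 (SE 1.41, limma adjusted p 0.000236) and probe 3226.C fell by 6.84 (SE 0.86, limma adjusted p 4.14e-07). The adjusted p of 9383.E was 0.188 when changes from the own 0 min arrays were compared. 228 called probes were well above background on all control arrays and on no MgProto array at 60 min. Of the 4348 called probes, 3108 were well above background on all arrays of both groups. Slide as a block gave 5525 calls, and within the 3 slides that held both groups 97.5% to 100% of the called probes had the pooled direction. Slide 1 alone gave 4770 calls, 3969 of them also called with all arrays. Its arrays are among those behind the full calls, so this overlap too is no replication. 2501 probes were called against the own 0 min arrays.

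At 120 min with MgProto 439 probes were higher and 176 lower than control, 615 of 8451 tested. Probe 9381.E (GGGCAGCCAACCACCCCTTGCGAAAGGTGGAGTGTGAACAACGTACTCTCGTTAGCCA) stood at 4.63 ± 1.30 (SD, n = 2) against -0.38 ± 1.38 (n = 4) in control, a change of 5.02 (SE 0.71, limma adjusted p 0.000181). Probe 7290.C (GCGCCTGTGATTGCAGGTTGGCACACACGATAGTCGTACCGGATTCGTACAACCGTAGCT) rose by 4.34 (SE 0.60, limma adjusted p 0.000169). Probe 8235.D fell by 4.67 (SE 1.24, limma adjusted p 0.0227) and probe 5675.C fell by 3.56 (SE 1.09, limma adjusted p 0.0486). With MgProto at 60 min probe 9381.E had already risen by 8.21 (SE 0.58, limma adjusted p 9.70e-11). It was saturated on 1 of 4 MgProto arrays there, so the rule did not print it. The count rested on single arrays: it was 361 without array 2 of control 120 min, 395 without array 1 and 44 without array 2 of MgProto 120 min, 16 with the compared groups alone in the fit and 6 against the own 0 min arrays, and in these last 2 settings none of the 4 printed probes was called. With slide as a block it was 1456, and on the 1 slide that held both groups 100% of the called probes had the pooled direction.

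At 180 min with MgProto 52 probes were higher and 9 lower than control of 8452 tested. Probe 9381.E stood at 4.26 ± 1.91 (SD, n = 2) against -1.55 ± 0.10 (n = 2), a change of 5.81 (SE 0.82, limma adjusted p 0.00121), and probe 7290.C rose by 4.78 (SE 0.70, limma adjusted p 0.00143). Probe 4033.C fell by 2.27 (SE 0.52, limma adjusted p 0.0364) and probe 2488.C fell by 2.22 (SE 0.52, limma adjusted p 0.0423). 961 probes had an unadjusted p under 0.05. Without array 2 of MgProto 180 min limma called 0 probes, with 447 at an unadjusted p under 0.05. The count was 155 without array 1 of that group and 27 without array 1 of control 180 min. With the compared groups alone, or against the own 0 min arrays, limma called 0 probes, with 575 and 335 at an unadjusted p under 0.05. Slide as a block gave 545 calls, with 100% of the 61 probes in the pooled direction on each of the 2 slides that held both groups, which are the arrays that gave the calls.

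**Figure D2:**
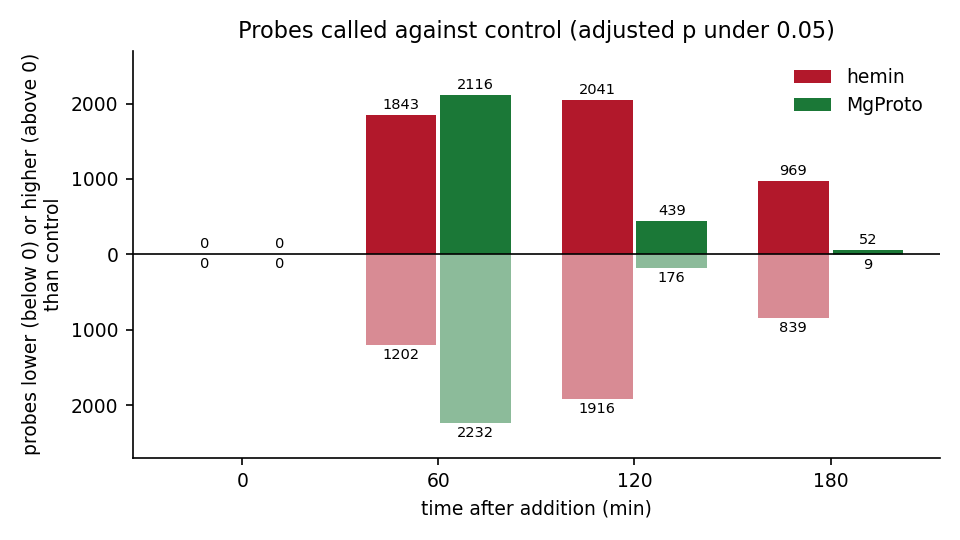
Number of probes called higher (bars above 0) and lower (bars below 0) than control at each time after addition, for hemin and MgProto, by limma with Benjamini-Hochberg adjusted p under 0.05. Hemin gave 1843 higher and 1202 lower at 60 min and 969 and 839 at 180 min, and MgProto 2116 and 2232 at 60 min and 52 and 9 at 180 min.

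The MgProto response was smaller at later times, and the difference was tested directly. To measure size on probes not chosen by the effect itself, changes with MgProto were read on the probes called with hemin at 60 min, and the reverse, although at 60 min both share the control arrays. On the 1843 probes higher with hemin the median log2 change with MgProto was 1.68, 0.69 and 0.42 at 60, 120 and 180 min, and on the 1202 lower probes it was -2.43, -0.58 and -0.48. On the 2116 probes higher with MgProto at 60 min the median change with hemin was 1.54, 1.58 and 1.11, and on the 2232 lower probes it was -1.29, -1.72 and -1.17. By limma, the MgProto effect differed between 60 and 120 min at 1437 probes and between 60 and 180 min at 1432, with adjustment by Benjamini-Hochberg. For hemin these counts were 77 and 132. The compound by time interaction called 1746 probes for 120 against 60 min and 924 for 180 against 60 min. Between 120 and 180 min 0 probes differed for either compound by limma, with 435 at an unadjusted p under 0.05 for hemin and 75 for MgProto. With arrays 1, 2 and 4 of the groups of 4 averaged and a replicate block, limma called 0 probes for the hemin effect between 60 and 120 min, with 644 at an unadjusted p under 0.05, and 227 between 60 and 180 min.

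**Figure D3:**
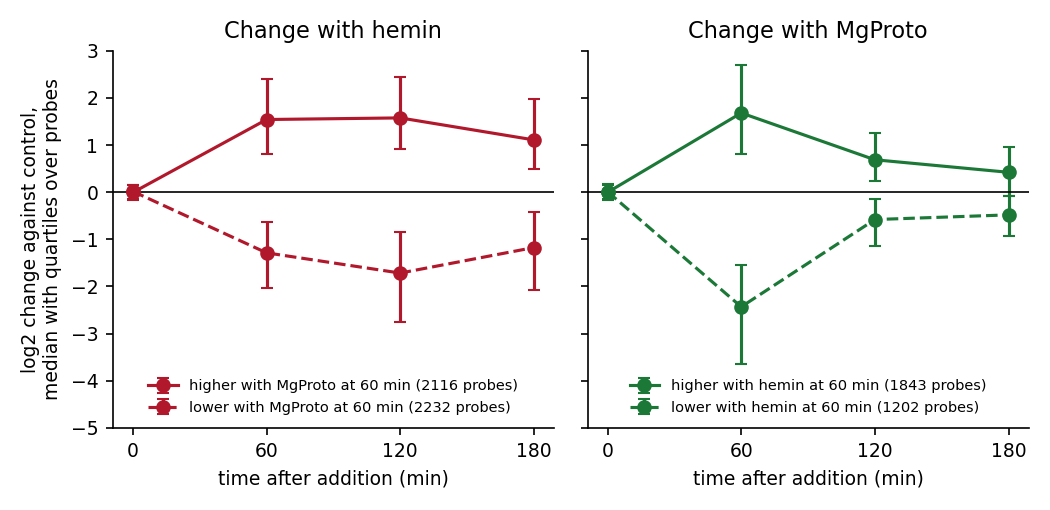
Median log2 change against control, with quartiles over probes, by time after addition (min), for each compound on the probes called higher or lower with the other compound at 60 min. With MgProto the median on the higher set goes from 1.68 at 60 min to 0.42 at 180 min, and with hemin from 1.54 to 1.11.

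**Figure D4:**
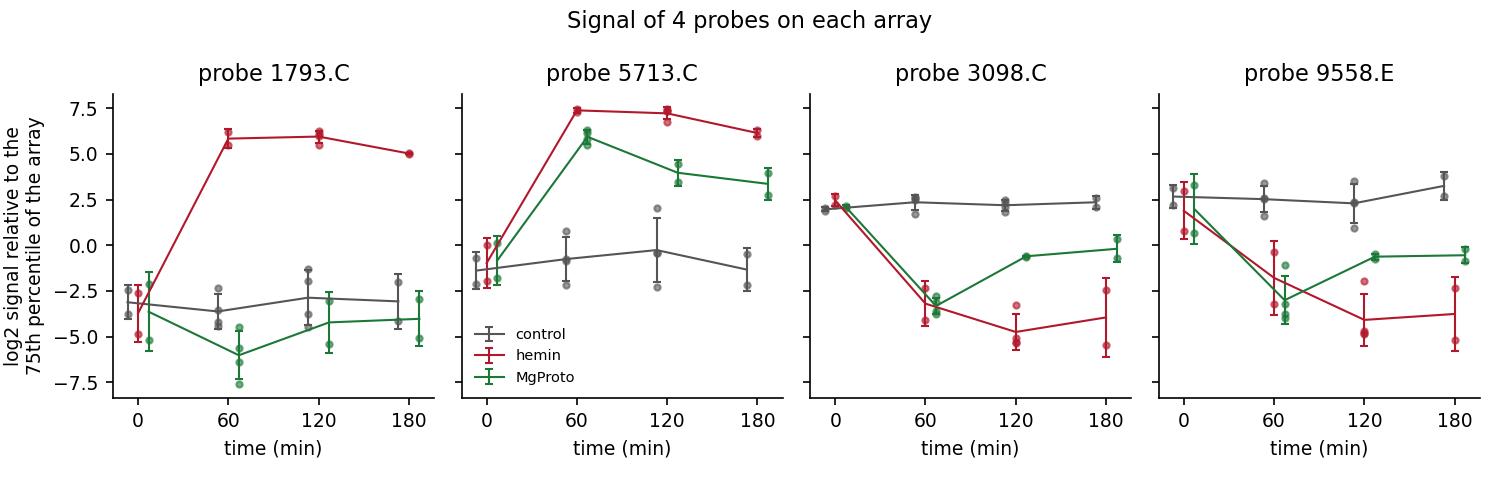
Log2 signal relative to the 75th percentile of the array, by time (min), for probes 1793.C, 5713.C, 3098.C and 9558.E, with a point per array and the mean ± SD for control, hemin and MgProto. With hemin, probe 1793.C stands at 5.84 at 60 min and 5.02 at 180 min, and with MgProto at -6.02 and -4.03.

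The compounds moved many of the same probes in the same direction. At 60 min 1360 probes were higher with both, where independent lists would share 460, and 1057 were lower with both, where independent lists would share 317. At 120 min 411 were higher and 158 lower with both (106 and 39.9 for independent lists), and at 180 min 51 and 7 (5.96 and 0.892). These lists were called against the same control arrays, which by itself raises their overlap. By how much was not simulated for these counts. Across probes the changes with the 2 compounds correlated at 0.78, 0.75 and 0.78 at 60, 120 and 180 min, against 0.41, 0.41 and 0.50 for unchanged groups set against the same controls, and probes are not independent replicates. The covariance was 2.39, 1.26 and 1.01, against 0.14, 0.14 and 0.28 in the simulation. With the control arrays divided between the compounds the correlation was 0.55 to 0.79 at 60 min and 0.44 to 0.73 at 120 min. At 180 min the controls were too few to divide, and part of the excess there may come from the shared controls. Counting all times, 4683 probes were called with hemin and 4385 with MgProto, 3589 with both, and 64.6% of the 8475 probes with at least 1 of them.

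At matched dose and time the compounds also differed. At 60 min 924 probes were higher and 423 lower with hemin than with MgProto. Probe 7678.D (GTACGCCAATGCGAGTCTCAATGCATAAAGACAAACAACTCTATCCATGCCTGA) stood at 4.22 ± 0.15 (SD, n = 2) with hemin, -5.20 ± 0.69 (n = 4) with MgProto and -2.47 ± 0.31 (n = 4) in control, a difference between the compounds of 9.43 (SE 0.40, limma adjusted p 7.92e-14) or 688-fold. Probe 2897.C was higher with hemin by 5.63 (SE 0.30, limma adjusted p 5.12e-12). Probe 1084.C had a difference of -5.56 (SE 1.62, limma adjusted p 0.0206, but 0.236 without array 2 of hemin 60 min and 0.375 against the own 0 min arrays) and probe 329.A of -5.07 (SE 0.56, limma adjusted p 1.38e-06). Of the 2417 probes called in the same direction with both compounds, 449 differed in size, 82 more strongly changed with hemin and 367 with MgProto. 37 probes were called in opposite directions, 29 of them higher with hemin and lower with MgProto. All 37 were also called for the difference, which opposite calls against the same controls made nearly certain in advance. Their number was 36 with quantile normalization, 24 of these among the 37. The share higher among called probes was 68.6%, and 53.0% with quantile normalization, which moved the median difference of all probes from 0.35 to 0.03. The count was 374 without array 2 of hemin 60 min, 2025 without array 3 of MgProto 60 min, 154 with the compared groups alone in the fit, 176 against the own 0 min arrays and 2647 with slide as a block. On the 1 slide that held both groups 99.9% of the called probes had the pooled direction.

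At 120 min 800 probes were higher and 1012 lower with hemin than with MgProto. Probe 1793.C was higher with hemin by 10.17 (SE 1.01, limma adjusted p 6.01e-07) and probe 7678.D by 6.90 (SE 0.40, limma adjusted p 7.75e-11). Probes 9815.E and 3098.C had differences of -4.20 (SE 0.63, limma adjusted p 0.000101) and -4.14 (SE 0.63, limma adjusted p 0.000108), and both had fallen with hemin. Of 569 probes called in the same direction with both, 261 differed, 259 of them more strongly changed with hemin. The count was 1154 without array 1 of hemin 120 min, 612 without array 1 and 1065 without array 2 of MgProto 120 min, 475 with the compared groups alone, 142 against the own 0 min arrays and 3350 with slide as a block. No slide held arrays of both groups.

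At 180 min 112 probes were higher and 92 lower with hemin than with MgProto. Probe 1793.C was higher with hemin by 9.05 (SE 1.16, limma adjusted p 6.05e-05) and probe 7678.D by 5.51 (SE 0.46, limma adjusted p 8.70e-08). Probe 6274.C had a difference of -3.98 (SE 0.44, limma adjusted p 9.58e-06) and probe 3098.C of -3.76 (SE 0.72, limma adjusted p 0.00519, but 0.252 without array 1 of hemin 180 min). The count was 43 without array 1 of hemin 180 min, 30 without array 1 of MgProto 180 min, 31 without the 3 arrays whose paired spots differed most, 15 against the own 0 min arrays and 1588 with slide as a block. With the compared groups alone limma called 0 probes, with 980 at an unadjusted p under 0.05. On the 1 slide that held both groups 100% of the called probes had the pooled direction. Most probes were neither called different nor shown to be alike: the 95% interval of the difference reached a median of 1.09, 1.09 and 1.26 log2 units to either side at 60, 120 and 180 min, and it lay within 1 unit of 0 for 9.999%, 7.60% and 7.37% of probes.

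**Figure D5:**
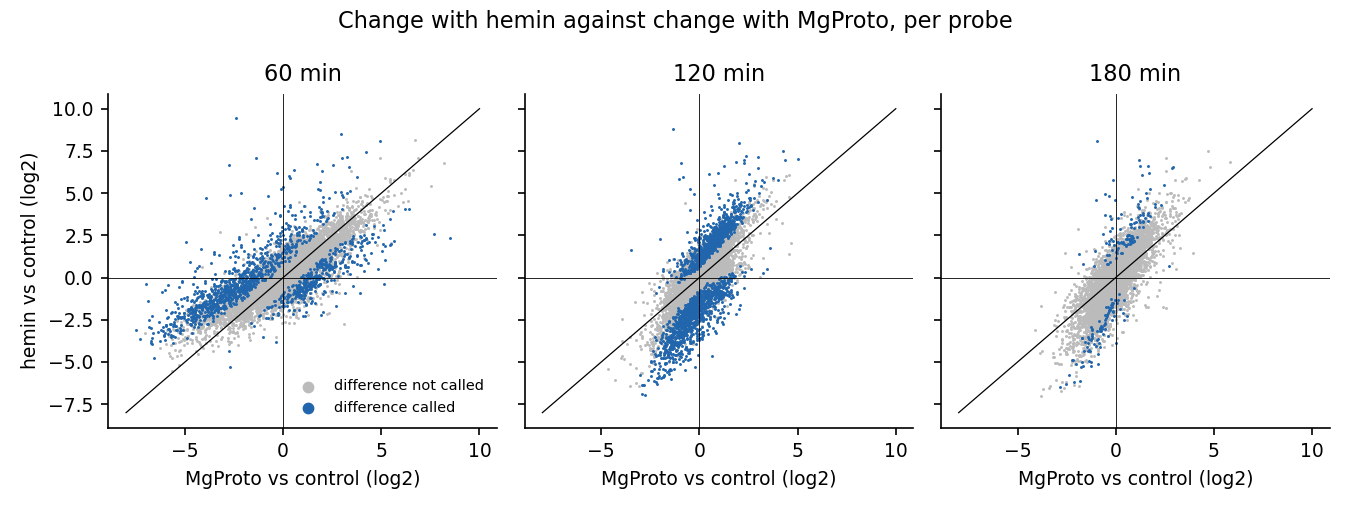
Log2 change against control with hemin (y axis) against that with MgProto (x axis) for each probe at 60, 120 and 180 min, with probes called different between the compounds in blue. The correlation is 0.78, 0.75 and 0.78, and 1347, 1812 and 204 probes are called different.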

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

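The tests of the array response, GC content, slide and runs of the experiment in this part were chosen only after the result was seen. So was the comparison of brighter with dimmer probes. The bounds for the brighter probes alone were set before.

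The MgProto effect differed between times. It was smaller at 180 than at 60 min, with 1432 probes called for the difference by limma, and 1437 for 60 against 120 min. Hemin and MgProto differed in their course at 924 probes for 180 against 60 min and at 1746 for 120 against 60 min. The smaller number of arrays at 180 min does not account for the fall, since the lowest count over the 36 choices of 2 MgProto and 2 control arrays at 60 min was 2877 calls against 61 at 180 min. The noisiest arrays stay open as a part of it. Without array 1 of control and of MgProto at 180 min, which leaves 1 array a group, the slope of the 180 min effects on the 60 min effects rose from 0.29 to 0.418. That is under the bound of 0.5 set before, but by less than the SD of 0.123 over the 4 choices of 1 MgProto and 1 control array, a spread added after the value was seen. These slopes ranged from 0.147 to 0.418 for MgProto and from 0.594 to 0.792 for hemin. With all arrays the slope was 0.69 for hemin and 0.29 for MgProto, a difference of 0.409, which is consistent with a response to MgProto that fades sooner. That remains a hypothesis, found and tested on the same data, and the uptake and loss of the compounds were not measured here.

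The second pattern sets the same array signals against the spike-in RNA, which the main comparisons do not use. It is therefore not independent of the called changes. Against the spike-in RNA, the 90th percentile of the signals was higher by 0.51 (SD 0.24, 4 pairs on the same slide) at 60 min with MgProto than in control, while the 75th percentile differed by -0.36 and the median by -1.04 (SD 0.33). The exact two-sided sign-flip p was 0.125 for each, the smallest that 4 pairs allow. These are shifts of percentiles of the signals on an array, not typical changes per probe. The median changes per probe given below were smaller than the shift of the median signal, and they do not measure the same fall. A steeper response of the treated arrays is argued against only in the range of the 4 spike-in probes used. There the slope of the spike-in signals on their level differed by -0.00465 (SD 0.0445, 4 pairs) between MgProto and control. Signals dimmer than these spike-in probes are not covered. A loss of signal near the background alone stays open, because the 5000 brighter probes changed by a median of -0.249 on the log2 scale, between the bounds set for and against it. The 5000 dimmer probes changed by -0.0699, less than the brighter ones and so the reverse of such a loss, but brighter minus dimmer was -0.137 with an SD of 0.145 over the 4 pairs, and signals near the floor can fall little. GC content stays open too, with a difference of 0.334 in the median log2 change between the 899 probes highest and the 984 lowest in GC content, and changes of -0.00252 and -0.34 against the spike-in in these sets. For hemin at 60 min the difference in the median log2 change by GC content was larger, at 0.832.

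The third pattern concerns array 3 of the groups of 4. Of 39 sets of 4 values tested for an outlying array, 7 had one, and 6 of the 7 were array 3. Chance gives about 1 in 20 for a single set. The sets were read on the same arrays and are not independent, so the number of flags does not measure chance. The 75th percentile against the spike-in was -0.23 on array 3 of control 120 min and -0.20 on array 3 of hemin 120 min, above the rest of each group. Probe 3098.C stood at -3.29 and probe 9558.E at -1.98 on array 3 of hemin 120 min, probe 3226.C at -2.98 on array 3 of MgProto 60 min and probe 5675.C at 0.26 on array 3 of control 120 min, each above the rest of its group. The slide stays open. In hemin 120 min, arrays 3 and 4 on the same slide differed by 0.2004 more than arrays 2 and 4 on different slides, but that is 1 group, and arrays 1 and 4 differed as much. In the other 3 groups array 3 is the only array on its slide, so slide and array 3 cannot be told apart there. A candidate explanation is that array 3 came from another run of the culture experiment than arrays 1, 2 and 4, since on slide 4 the signal against the spike-in split the arrays with a gap of 0.897, with array 3 of hemin 120 min beside array 2 of hemin 0, 60 and 180 min and apart from the arrays numbered 4. A run of the cultures and a batch of labelling would look alike here.

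The remaining results are given as values. Probe 3098.C stood at 1.74 on array 1 of control 60 min, below the rest of that group. The hemin effect differed between 60 and 180 min at 132 probes and between 60 and 120 min at 77. 37 probes were called in opposite directions with hemin and MgProto at 60 min.

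Other divisions of the same arrays were also tried for both comparisons with 4 arrays a group, taking arrays as separate samples. For MgProto at 60 min, 1 of 35 splits of the 8 arrays, the real one, gave as many as 4348 calls, and the highest other gave 831. For hemin at 120 min it was again 1 of 35, with 3957 calls against 1906 for the highest other. If the numbers pair the arrays, the like splits are the 8 that part all 4 pairs, too few for a share under 0.05. Among them the 7 others gave 0 calls by limma in both comparisons. Splits that mix treated and control arrays put the treatment change into the spread. Few calls were therefore likely in advance, and these counts do not measure chance.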

How the results depend on the processing

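Under the authors' log2 values each of the 13 counts stayed within 1.5 times its value, and the block on the numbers 1 to 4 gave 5025 calls for hemin at 120 min and 5282 for MgProto at 60 min, neither moved by more than 1.5 times. Of 709 refits of the 36 probe results printed by the rule, 641 remained called, 68 kept the direction and lost the call, and 0 were reversed. The rule picked large changes whose arrays did not overlap between the groups. Leaving out or averaging arrays could therefore not reverse them, and the lack of reversals is no test of the direction. Against control 54 of 481 lost the call, most of them for probes 2488.C, 4033.C, 5675.C and 8235.D, which fell with MgProto at 120 or 180 min, and the others for 6066.C, 7290.C, 9381.E and 9383.E. Between the compounds 14 of 228 did, 6 of them for 1084.C at 60 min and the rest for the probes printed at 180 min. Leaving out 1 array moved the fold of 17 of the 36 by more than 1.5 times. The settings named below moved counts by more than 1.5 times, and the cause was not tested unless stated. Comparing changes from the own 0 min arrays, which adds the spread of 2 more groups, gave for hemin 1240, 2023 and 523 calls at 60, 120 and 180 min, for MgProto 2501, 6 and 0, and between the compounds 176, 142 and 15. The compared groups alone, which leaves fewer arrays to estimate the spread, gave 351 for hemin at 180 min, 16 and 0 for MgProto at 120 and 180 min, and 154, 475 and 0 between the compounds. With arrays 1 and 2 and arrays 3 and 4 averaged, which leaves fewer samples, the counts were 2632 for hemin at 120 min, 131 and 30 for MgProto at 120 and 180 min, and 721, 1049 and 103 between the compounds. With arrays 1, 2 and 4 averaged, chosen after seeing the data, they were 2331, 68 and 16, and 457, 440 and 65. Adding a replicate block to that design gave 2873 for hemin, 184 for MgProto and 679 between them at 180 min. Slide as a block gave 3341 for hemin at 180 min, 1456 and 545 for MgProto at 120 and 180 min, and 2647, 3350 and 1588 between the compounds. The replicate block on sample 1 or 2 gave 1245 and 231 for MgProto at 120 and 180 min and 2650 and 610 between the compounds at 60 and 180 min. In the comparisons with 2 shared numbers the check settles no pairing: equally numbered arrays correlated at 0.84, 0.90 and 0.88 at 0 min and at 0.28, 0.54 and 0.18 at 180 min, each 1 independent value, and between groups of 2 and 4 arrays number 1 correlated at 0.05 to 0.49 and number 2 at -0.40 to -0.24. The averaged arrays 1, 2 and 4 with a block stand for another pairing.

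Normexp with quantile normalization gave 261 for MgProto and 454 between the compounds at 180 min, and quantile normalization alone gave 323 for the latter. The stricter filter gave 100 for MgProto at 180 min, and no filter gave 1 for hemin at 0 min. Without the 3 arrays in doubt, a choice made after seeing the data, 31 probes differed between the compounds at 180 min. Scaling on the spike-in with the averaged arrays and block, also chosen then, gave 2947 for hemin, 557 for MgProto and 467 between the compounds at 180 min, and 1957 for MgProto at 120 min. It moved the median of all probes to 0.58 for hemin at 180 min and to -0.38, 0.73 and 0.36 for MgProto at 60, 120 and 180 min. Against the same averaged arrays and block scaled on the percentile, the share higher among called probes became 77.7% from 48.8% for hemin at 180 min, and for MgProto 33.4% from 49.0% at 60 min, 94.6% from 54.6% at 120 min and 96.1% from 57.6% at 180 min. Between the compounds it became 92.4% from 70.7% at 60 min, 5.71% from 47.5% at 120 min and 58.5% from 46.7% at 180 min. With all 32 arrays separate these shares were 53.6%, 48.7%, 71.4%, 85.2%, 68.6%, 44.2% and 54.9%. Normexp with quantile normalization gave 69.7% for MgProto at 180 min, and between the compounds at 60 min it and quantile normalization alone each gave 53.0%. The balance of rises and falls is therefore relative to the scaling, and it also moved with the averaging and block.

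Leaving out each array in turn gave for hemin 1599 to 3044 calls at 60 min, 3514 to 4016 at 120 min and 793 to 1659 at 180 min. For MgProto it gave 4064 to 4334, 44 to 525 and 0 to 155, and between the compounds 374 to 2025, 612 to 2168 and 30 to 254. For the 0 min comparisons the count was 0 each time, and for control over time it was 0 to 44. Where a group kept 1 array, that array was assumed to vary like the other groups. Averaging probes per gene and the gene list shifts were not run, because the files give no genes. Signal over background limits 3533 of the 8475 probes, which were not well above it on some array.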

Other observations

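Across probes the changes with hemin at 120 min and with MgProto at 60 min, which share no control arrays, correlated at 0.86, with a slope of hemin on MgProto of 0.77. These are the only 2 comparisons with 4 treated and 4 control arrays, while the pairs at equal times, at 0.75 to 0.78, include groups of 2 and share control arrays. The effect of group size was not tested. 435 of 8467 probes differed between these effects by limma, 369 of them higher with hemin at 120 min. The lowest correlation among the 6 comparisons was 0.46, between hemin at 60 min and MgProto at 180 min. Probes are not independent replicates, and no test of the difference between these correlations was run.

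Some probes parted the compounds. Probe 1793.C, which rose 705-fold with hemin at 60 min, fell by 2.40 with MgProto at that time (limma adjusted p 0.0174). It was well above background on only 1 of 4 MgProto arrays there, so this fall is not a measured size. The 29 probes called higher with hemin and lower with MgProto at 60 min had median log2 changes of 1.94 and -1.53 there, and of 0.90 with hemin and -0.48 with MgProto at 120 min. Probe 4033.C rose by 3.66 with hemin at 60 min (SE 0.45, limma adjusted p 1.19e-06) and by 1.44 at 120 min (SE 0.37, limma adjusted p 0.00226), while with MgProto its change was -0.19 at 60 min (limma adjusted p 0.708) and -2.27 at 180 min (limma adjusted p 0.0364). With hemin at 180 min its change was -0.72 (limma adjusted p 0.372), and the compounds were not called different there (limma adjusted p 0.117). These probes were taken up here after their values were seen, except where the rule for printed probes had given them.

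Only 2 probe names hold a word. The probe whose name ends in PilA1 rose by 3.04 with hemin at 60 min (SE 0.89, limma adjusted p 0.00997) and by 1.92 at 120 min (SE 0.72, limma adjusted p 0.0329), but was well above background on only 1 of 4 control arrays at each time and 2 of 4 hemin arrays at 120 min, so these are not measured sizes. At 180 min, where it was above background on all arrays of both groups, it was not called (change 1.29, SE 1.02, limma adjusted p 0.427). Its change with MgProto at 60 min was 0.55 (SE 0.72, limma adjusted p 0.561). The probe ending in PHOX was well above background on no control array at 60, 120 or 180 min.

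The other probe names end in 1 of 5 letters whose meaning is not given in the sources used here. Called probes were spread unequally over them by Fisher's exact test with Benjamini-Hochberg adjustment. Of probes ending in D, 31.8% were lower with MgProto at 60 min, against 25.4% of the others (odds ratio 1.37, adjusted p 8.88e-05), and 28.1% were lower with hemin at 120 min, against 21.6% (odds ratio 1.41, adjusted p 5.11e-05). Of probes ending in E, 15.7% were higher with hemin at 180 min, against 10.9% of the others (odds ratio 1.53, adjusted p 0.000239). The test takes probes as independent, which probes of a shared pathway are not.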
